A study of Mus musculus with 8 samples.

How the data were processed

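RNA was measured in 8 mouse hearts, 4 from homozygous Pus1 mutants and 4 from wild-type animals, on 4 Agilent 2-colour whole-genome arrays. Per the labels, each array held 1 mutant and 1 wild-type heart of the same sex, arrays 1 and 2 females and arrays 3 and 4 males. The mutant was in Cy5 on arrays 1 and 3 and in Cy3 on arrays 2 and 4, so that both dye orientations occurred in each sex. Per the labels, the animals were on a C57BL/6J background after 5 generations of backcrossing and were 14 to 16 weeks old, a piece holding atrium and ventricle was taken, and 100 ng of RNA was labelled. The labels do not describe the altered allele.

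Per the file headers, the authors scanned the 4 arrays on 1 slide in 1 scan and extracted spot values with Agilent Feature Extraction 10.7.3.1 on a grid annotated for mouse build mm9. With a single slide and a single scan there was no batch to test. The deposited intensity values used here were the median pixel brightness of each spot and of its local background, neither corrected nor normalized, per the file headers. Mean spot signals had been planned, and the median signals were used in their place because the files gave spot brightness as medians. Processed intensity values, background-subtracted and dye-normalized by Feature Extraction per the file headers, served as an alternative, as did the authors' deposited series matrix of log2 values. The source of the matrix's normalization was not given in the sources used here. Its columns all had a mean of 0.021, each probe was centred on its median over the 8 samples, and column medians were 0.01, 0.00, -0.01 and -0.01 for Cy3 and 0.00, 0.01, 0.06 and -0.02 for Cy5 on arrays 1 to 4. The Cy5 minus Cy3 difference of the matrix correlated across 28528 probes with the log2 ratio of processed signals at 0.997, 0.997, 0.991 and 0.998, with slopes of 0.988 to 1.04, which settled its scale and direction.

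Each array held 62976 spots, 3671 of them controls, and 55681 distinct probes that were not controls. Background was corrected with normexp and an offset of 50, and log2 ratios were normalized within arrays by loess with control spots and non-uniform spots at weight 0, in limma 3.58.1 under R 4.3.3. Non-uniform spots were then set missing and repeated spots of a probe averaged. A probe was kept when Feature Extraction called it well above background in at least 4 of the 8 samples, which left 28528 probes. Accessions were named through a RefSeq gene table of the assembly GRCm38.p6. Of 23171 RefSeq accessions on the array 21865 had a symbol, so that 27656 probes had 1 gene symbol and 28025 had none and kept their accession. The same table served for which genes lie near each other, and none of its coordinates are printed because the files use another build. For a gene with several probes the one with the highest mean log2 intensity was taken, which gave 21792 features, 13692 of them named genes.

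Ratios were turned to mutant over wild type and fitted with limma (lmFit and eBayes) with a genotype coefficient and a probe-specific dye term, the array being the block because the ratio was taken within it. The difference between females and males, and the effect in each sex, came from the same kind of fit with a genotype by sex term, which left 1 residual degree of freedom against 2 in the genotype fit. Tests were 2-sided, with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. Gene lists were tested with limma's camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry. Of 49 lists, 44 had at least 5 measured members and were tested. Levels per sample came from the separate channels after loess and Aquantile normalization. Deviations of the samples of a pair from their genotype means correlated across features at -0.49, -0.11, -0.38 and 0.50 on arrays 1 to 4. The pairing itself comes from the labels, which put both samples on one array.

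The design, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took Pus1, then the genes past the threshold with the largest change and the same sign on all 4 arrays, up to 12 per direction. Where fewer passed, it took up to 6 per direction of the genes with the smallest p and the same sign on all 4 arrays, given as not past the threshold. For the difference between sexes it took up to 6 per direction of the largest changes past the threshold. The condition on signs was read there as both female ratios lying on one side of both male ratios. Up to 4 members with the smallest p were taken from a list, and other genes are said to have been chosen after their values were seen.

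On data simulated for the genotype comparison over 21792 features, the fit recovered 0%, 42%, 94% and 98% of features changed by 0.5, 1, 2 and 3 on the log2 scale, with 12 false calls among 129. For the genotype by sex comparison it recovered 0% at each of these sizes. The noise was drawn independently per feature with the moderated spread of the genotype fit, which holds any difference between sexes. These percentages are therefore not the power of the reported fits. In the data Pus1, at -1.85, did not pass between genotypes, whereas the genotype by sex fit called 2035 features. The number of arrays limits the precision. Of the probes, 44.7% to 54.6% were well above background per sample, and the spread of red negative-control spots lay outside Feature Extraction's own range on all 4 arrays. Alternatives covered background correction, normalization, the series matrix, the filter on dim probes, the choice of probe, the dye term, the array block, the prior variance, array weights and leaving out each pair. One more, restricting the probes to RefSeq messenger RNAs, was chosen after seeing the data.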

Results

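Gene expression was compared between hearts of 4 homozygous Pus1 mutant mice and 4 wild-type mice, 2 females and 2 males of each genotype, on 4 2-colour arrays that each held a mutant and a wild-type heart of one sex. Pus1 encodes a pseudouridine synthase, which converts uridine to pseudouridine in transfer RNAs of the cytosol and the mitochondria. The share of probes well above background was 46.3%, 49.5%, 50.9% and 53.8% in wild-type replicates 1 to 4 and 54.6%, 49.4%, 44.7% and 52.4% in mutant replicates 1 to 4. The sex of the labels was borne out by the sex-linked genes. Xist, transcribed from the inactive X chromosome, was well above background in 4 of 4 females (9.61 ± 0.34, SD, n = 4, normalized log2 intensity of the brighter probe) and in 0 of 4 males. Ddx3y, a Y-linked helicase gene, was well above background in 4 of 4 males (10.76 ± 0.12, SD, n = 4) and in 0 of 4 females. Eif2s3y, another Y-linked gene, stood at 11.41 ± 0.07 (SD, n = 4) in males and 7.41 ± 0.26 (SD, n = 4) in females. The probes of Uty and Kdm5d, also Y-linked, were dim in both sexes.

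The first comparison asked what differs between Pus1 mutant and wild-type hearts. Pus1 itself was lower in the mutant on every array. Its single probe stood at 9.10 ± 0.15 (SD, n = 4) in wild type and 7.25 ± 0.22 (SD, n = 4) in mutants on the normalized log2 scale, and it was well above background in all 8 samples. The mutant over wild-type log2 ratios were -2.15, -1.68, -1.69 and -1.88 on arrays 1 to 4, a mean of -1.85 (SE 0.13), or 3.61-fold lower. Where the probe lies relative to the altered part of the gene is not given by the labels. Pus1 did not pass the threshold over all features in the limma fit (adjusted p = 1.00). It passed with a sex by genotype term in the fit (adjusted p = 0.00577), with median centring (0.0242), with separate channels and no replicate block (0.0292) and with the array as a random block (0.0286), and its adjusted p ran from 0.00577 to 1.00 over the alternatives.

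**Figure D1:**
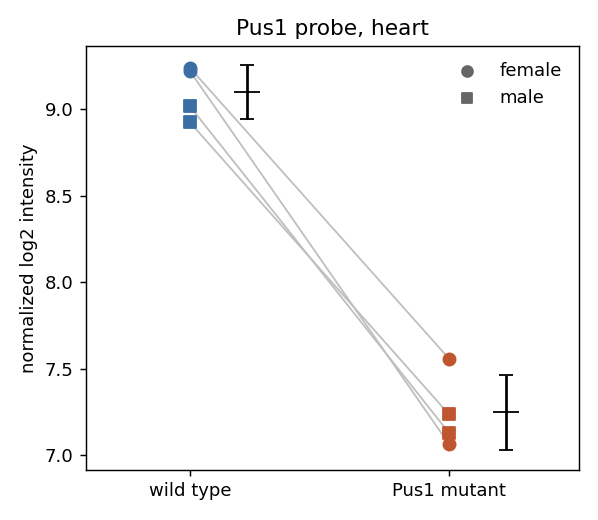
Normalized log2 intensity of the Pus1 probe (y axis) in wild-type and Pus1 mutant hearts (x axis). Circles are females, squares are males, grey lines join the samples of one array, and bars give the mean and SD (n = 4), 9.10 ± 0.15 in wild type and 7.25 ± 0.22 in mutants.

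No feature of the 21792 passed adjusted p 0.05 between genotypes in the limma fit, and 223, or 1.02%, had an unadjusted p under 0.05. This is less than the share of 0.05 to be had with no true difference, so that the fit was conservative. Its residual holds any difference between sexes, and with a sex by genotype term 502 features had an unadjusted p under 0.05. The absence of calls therefore does not show that genotype changed little. The 6 genes with the smallest p and a positive ratio on all 4 arrays did not pass the threshold. They were Ift81, a component of the intraflagellar transport machinery of cilia (log2 ratio 1.06, SE 0.12), Sparcl1, a secreted matrix glycoprotein (0.73, SE 0.11), and the chemokine gene Ccl12 (0.70, SE 0.11). The others were Tesc, which encodes the calcium-binding protein tescalcin (0.64, SE 0.10), Rnf208, a RING finger gene (0.58, SE 0.11), and Meox1, a homeobox gene (0.50, SE 0.10). Tesc had the most even ratios of these, 0.66, 0.74, 0.55 and 0.61 on arrays 1 to 4, and Ift81 ranged from 0.40 to 1.67. The SD of the 4 ratios was 0.08 for Tesc, 0.58 for Ift81 and 0.54 for Ccl12, and the SE leave out the part that follows the dye. A dimmer probe of Rnf208 gave 0.49, -0.18, 0.56 and 0.39. Ccl12 was not well above background in wild-type replicate 1. Over the alternatives its ratio ran from 0.65 to 1.42, and that of Rnf208 from 0.45 to 1.18.

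The 6 genes with the smallest p and a negative ratio on all 4 arrays did not pass either. They were Pxmp2, a peroxisomal membrane channel (log2 ratio -0.73, SE 0.12), P2rx7, an ATP-gated ion channel (-1.13, SE 0.19), and Cngb3, a cyclic nucleotide-gated channel subunit (-0.73, SE 0.13). The others were Angptl4, a secreted inhibitor of lipoprotein lipase (-0.86, SE 0.18), Kcnv2, a potassium channel subunit (-0.42, SE 0.10), and Rspo1, a secreted activator of Wnt signalling (-0.65, SE 0.16). The ratios of Cngb3 ran from -1.40 to -0.15 (SD 0.56) and those of Angptl4 from -1.53 to -0.04 (SD 0.63). The probes of P2rx7 disagreed. The brightest gave ratios from -1.57 to -0.60, whereas 2 dimmer ones gave means of -0.07 and 0.02. Of these 12 genes 5 (Ift81, Sparcl1, Tesc, Pxmp2 and P2rx7) lie within 20 Mb of Pus1 in the assembly GRCm38.p6, a stretch that held 306 of the measured genes.

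**Figure D2:**
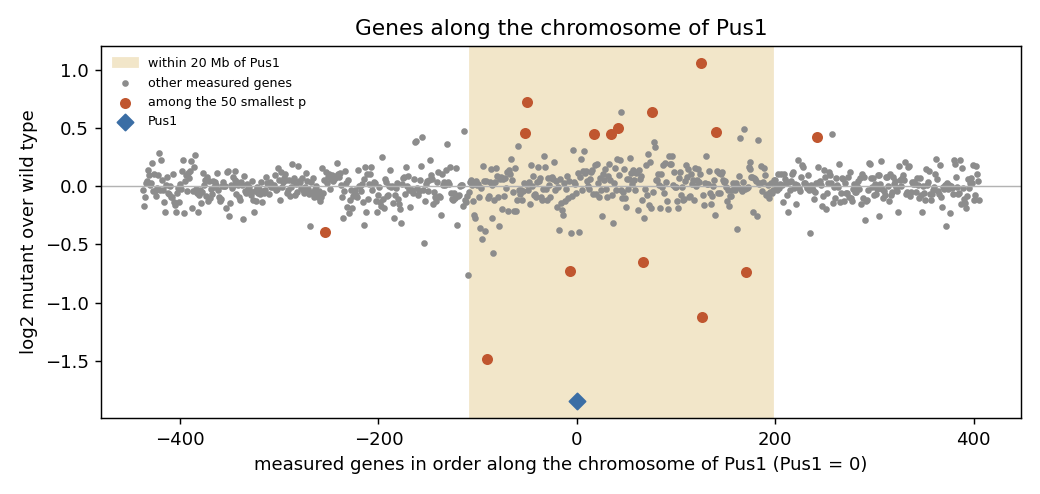
Mutant over wild-type log2 ratio (y axis) of the 843 measured genes on the chromosome of Pus1, in their order along it (x axis, Pus1 at 0). The shaded stretch lies within 20 Mb of Pus1, and filled orange points are genes among the 50 with the smallest p between genotypes, 13 of which fall in that stretch.

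Ratios of single arrays hold the dye effect as well. For dye, 2157 features, or 9.90%, had an unadjusted p under 0.05 in the limma fit and 0 passed. Mutant over wild-type ratios of the 4 arrays did not run in parallel across features. Their correlations were 0.03 between the female arrays 1 and 2 and 0.31 between the male arrays 3 and 4. Between the sexes they were -0.32 (arrays 1 and 3), -0.49 (1 and 4), -0.69 (2 and 3) and -0.16 (2 and 4). The dyes of the labels set the direction, and the Pus1 probe was lower in the mutant on all 4 arrays.

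Pseudouridine synthases, other tRNA modification enzymes and subunits of the respiratory chain did not pass camera between genotypes. Of 12 measured pseudouridine synthases 7 had a positive and 5 a negative log2 ratio, and Pus1 was the member with the smallest p, while Pusl1, the next, was at 0.19 (SE 0.12, 0.09 to 0.29 when each pair was left out). Over all features 0 of the 12 passed. Adjusted over the list alone, 1 passed (Pus1, adjusted p = 0.000925). The median of the synthases was 0.05, which turned negative without replicate 3 and without replicate 4, and their mean, which Pus1 weighs on, was -0.12. The 42 other tRNA modification enzymes had a median of 0.00 and 0 passed. Of 36 complex I subunits of the respiratory chain 17 had a positive ratio, with a median of -0.01 and a mean of 0.01, and 0 passed over all features or adjusted over the list alone. The sign of this median turned with processed signals, series matrix values, median centring and without replicate 1. Median centring also moved the median of all features, from -0.01 in the reported fit to 0.08. Signs and upper ends of ranges under median centring are therefore not relative to the other features. The member with the smallest p was Ndufab1, the mitochondrial acyl carrier protein (0.31, SE 0.12). Subunits of complexes II and III (median 0.02), IV (-0.03) and V (0.02) and mitochondrial aminoacyl-tRNA synthetases (0.04) did not pass camera either. Of these small medians, those of the other tRNA modification enzymes, complex IV and complex V also changed sign, under 5, 3 and 1 of the alternatives. Of 13 genes for mitochondrially encoded proteins 0 were measured.

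Camera with a preset correlation called 19 of the 44 lists, 13 higher and 6 lower in the mutant. With an estimated correlation none was called, the smallest adjusted p being 0.725, nor did fry call any (smallest adjusted p = 0.166). In none of these 19 lists did a member pass over all features or adjusted over the list alone.

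The interferon response list led those called higher, with a positive ratio for 22 of 22 measured members and a median of 0.18 (adjusted p = 1.7e-08 in camera, 0.725 with an estimated correlation). Ifi27 (0.45, SE 0.12) and the transcription factor gene Irf7 (0.45, SE 0.14) were positive on all 4 arrays. The list's median was 0.39 and 0.21 on the female arrays and -0.07 and 0.03 on the male arrays, and ran from 0.01 to 0.32 over the alternatives. Of 20 cell cycle genes 17 had a positive ratio, with a median of 0.17 (adjusted p = 1.35e-05, 0.725 with an estimated correlation), with medians of 0.76, -0.15, 0.03 and -0.09 on arrays 1 to 4 and an overall median from 0.02 to 0.36 over the alternatives. The replication helicase subunit genes Mcm2 (0.53, SE 0.11) and Mcm3 (0.31, SE 0.11) had the smallest p among them. Of 22 glycolysis genes 18 had a positive ratio, with a median of 0.12 (adjusted p = 1.35e-05, 0.725 with an estimated correlation). The member with the smallest p went the other way, Pfkfb1, a regulatory enzyme of glycolysis (-0.30, SE 0.10). Next came Pfkl, a phosphofructokinase (0.26, SE 0.10), and Slc2a1, a glucose transporter (0.25, SE 0.10), each of mixed sign over the arrays. The median of this list ran from 0.10 to 0.21 over the alternatives. The 75 mitochondrial ribosomal proteins were called higher at a median of 0.05 (adjusted p = 0.000535, 0.725 with an estimated correlation), although the member with the smallest p, Mrpl23, was lower (-0.18, SE 0.10). The medians of this list on arrays 1 to 4 were 0.19, -0.12, 0.15 and 0.03, and the overall median ran from 0.00 to 0.18 over the alternatives. Cytosolic ribosomal proteins were called in the opposite direction, 63 of 75 being lower (median -0.04, adjusted p = 0.0291, 0.793 with an estimated correlation), and this median turned positive with median centring. It was 0.06 there, still below the 0.08 of all features.

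Genes induced by PPAR alpha and by fasting led the lists called lower. Of 18 members 14 had a negative ratio, with a median of -0.17 (adjusted p = 1.35e-05 in camera, 0.725 with an estimated correlation). The medians on arrays 1 to 4 were -0.11, -0.66, -0.13 and -0.09, and the overall median ran from -0.29 to -0.07 over the alternatives. Besides Angptl4 these were Txnip, an inhibitor of thioredoxin (-0.73, SE 0.17), Acot1, an acyl-CoA thioesterase (-0.87, SE 0.26), and Pdk4, a kinase that inactivates pyruvate dehydrogenase (-1.13, SE 0.44). On arrays 3 and 4 Txnip was at -0.93 and 0.01, Acot1 at -0.66 and -0.16 and Pdk4 at -0.35 and -0.13. When each pair was left out, Acot1 ran from -1.21 to -0.54 and Pdk4 from -1.63 to -0.63. Of 26 fatty acid oxidation genes 21 had a negative ratio, with a median of -0.06 (adjusted p = 0.0265, 0.793 with an estimated correlation), and the lists share Acot2, Cpt1a and Slc25a20. This median turned positive with median centring and without replicate 2. It was at most 0.04 over the alternatives, below the 0.08 of all features with median centring. Glucocorticoid targets, a list of handling and stress that shares Pdk4 with the fasting genes, were also called lower (median -0.17, adjusted p = 0.00560, 0.725 with an estimated correlation). Their medians on arrays 1 to 4 were -0.71, 0.09, -0.26 and 0.22, and the overall median ran from -0.26 to -0.04 over the alternatives. The 7 markers of epicardium and mesothelium all had a negative mean ratio (median -0.25, adjusted p = 0.00121, 0.725 with an estimated correlation), with Msln at -0.79 (SE 0.20) and Upk3b at -0.40 (SE 0.20). The medians of this list on arrays 1 to 4 were -0.41, -0.80, -0.20 and 0.17, the overall median ran from -0.60 to -0.03 over the alternatives, and Upk3b ran from -0.64 to -0.15 when each pair was left out.

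Markers of tissues that the piece of heart could hold in varying amounts differed widely between pairs. Of 18 atrial myocyte markers, a list that shares Upk3b with the epicardium list, 13 had a positive ratio (median 0.20, adjusted p = 4.28e-05, 0.725 with an estimated correlation), and the medians on arrays 1 to 4 were -0.22, 0.39, -0.04 and 0.68. Over the alternatives the median of this list ran from 0.16 to 0.29. The member with the smallest p was Stard10 (0.35, SE 0.11). Nppa, the atrial natriuretic peptide gene, had ratios of -0.76, 1.29, 0.79 and 1.97, and Dkk3 of 0.62, 0.40, 0.25 and 2.51. Their means ran from 0.43 to 1.21 and from 0.41 to 1.47 when each pair was left out. Of 15 adipocyte markers 12 had a positive ratio (median 0.23, adjusted p = 4.28e-05, 0.725 with an estimated correlation). Scd1, a fatty acid desaturase, had ratios of 0.05, 2.71, -0.04 and 1.58, and Cebpa had a mean of 0.30 (SE 0.11). The adipocyte medians on arrays 1 to 4 were -0.22, 0.68, 0.11 and 0.34, and the overall median ran from 0.12 to 0.44 over the alternatives. Erythroid genes had medians of 2.25, -2.16, -0.82 and 0.21 on arrays 1 to 4. Ventricular myocyte markers had a median of 0.02, which turned negative with probes well above background in all 8 samples and without replicate 4. Fetal and hypertrophic response genes, a list that shares Nppa and Myl4 with the atrial list, were called higher at a median of 0.08 (adjusted p = 0.0014, 0.725 with an estimated correlation), with the skeletal actin gene Acta1 at 0.44 (SE 0.12) and Cilp at 0.33 (SE 0.12), the median running from 0.06 to 0.26 over the alternatives. Fibroblast and matrix genes were called higher at a median of 0.08 (adjusted p = 0.000575, 0.725 with an estimated correlation), with Timp1 at 0.45 (SE 0.11) and Postn at 0.35 (SE 0.12), the median running from 0.04 to 0.19 over the alternatives. Other lists called higher were markers of macrophages and myeloid cells (median 0.03, adjusted p = 0.0233, 0.766 with an estimated correlation), of endothelial cells (0.04, 0.0174), smooth muscle and pericytes (0.08, 0.0233) and skeletal muscle (0.06, 0.0476), and oxidative stress response genes (0.08, 0.00411), the last 4 at 0.725 with an estimated correlation. The median turned negative without replicate 1 and without replicate 4 for macrophages, without replicate 3 for endothelial cells and without replicate 1 for skeletal muscle. It ran from 0.01 to 0.21 over the alternatives for smooth muscle and from 0.05 to 0.23 for oxidative stress. Lymphocyte markers were called lower, 11 of 12 being negative (median -0.14, -0.25 to -0.07 over the alternatives, adjusted p = 0.00505, 0.725 with an estimated correlation). Integrated stress response targets, at a median of 0.00, were not called, and their smallest-p members Asns (0.49, SE 0.10) and Psph (0.40, SE 0.12), both of amino acid synthesis, did not pass.

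**Figure D3:**
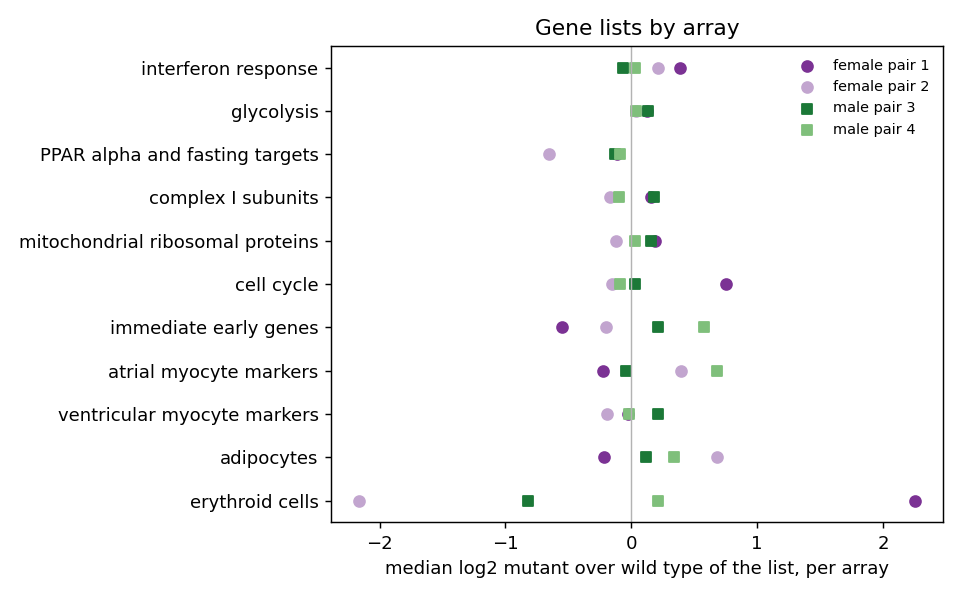
Median mutant over wild-type log2 ratio (x axis) of 11 gene lists (y axis) on each of the 4 arrays. Circles are the female pairs and squares the male pairs. Erythroid genes range from -2.16 to 2.25, whereas complex I subunits stay between -0.17 and 0.18. Ratios of single arrays are not adjusted for dye. The complex I medians were positive where the mutant was in Cy5 and negative where it was in Cy3.

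The second comparison asked whether the effect of genotype differed between females and males. In the limma fit with a genotype by sex term, 2035 features passed adjusted p 0.05, of which 2008 had a higher mutant over wild-type ratio in females than in males and 27 a lower one. In females 2 features passed, Pus1 (log2 ratio -1.92, adjusted p = 0.0429) and Pdk4 (-2.01, adjusted p = 0.0378). In males 737 passed, 18 higher and 719 lower in the mutant, and Pus1 was at -1.79 (adjusted p = 0.0311). These counts do not show a larger effect in males. Unadjusted p under 0.05 in this fit made up 12.1% of features in females and 13.8% in males. H2-Q4, for one, was at 2.34 in females (adjusted p = 0.0563 in limma) and -2.36 in males (0.0356). The counts of females and males each fell to 0 with no background correction. With scale normalization 894 passed in females, 868 of them higher in the mutant. With the mean over probes 2 passed in males, 2 of them higher. The difference for Pus1 itself was -0.13 in females minus males (adjusted p = 0.949), in a fit that could have missed one.

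Genes were named here only where both female ratios lay on one side of both male ratios. Among those with the largest difference, the 6 with a higher ratio in females were 4933438K21Rik (5.17 in females minus males on the log2 scale, SE 0.87), H2-Q4, a major histocompatibility class I gene (4.70, SE 0.65), Tssk5, a testis-specific kinase (4.56, SE 0.66), Gm10375 (4.47, SE 0.69), BC061237 (4.45, SE 0.65) and the Schlafen gene Slfn9 (4.05, SE 0.48). They moved in parallel, and the difference of 4933438K21Rik ran from 3.08 to 7.26 when each pair was left out. The probes of 4933438K21Rik and BC061237 were not well above background in mutant replicate 3. Their differences, and their place in this order, are therefore inexact. The ratios of H2-Q4 on arrays 1 to 4 were 2.86, 1.82, -3.66 and -1.06, and those of Slfn9 1.99, 2.00, -3.27 and -0.82. H2-Q4 belongs to a family of near-identical genes, so that its probe can bind transcripts of its relatives.

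Under the same condition, the 6 genes with the largest difference in the other direction were Nr4a1, an orphan nuclear receptor (-2.83, SE 0.31), Cfd, the adipocyte product adipsin (-2.42, SE 0.29), and Atf3, a transcription factor (-1.94, SE 0.29), followed by Pdk4 (-1.78, SE 0.27), Irs2, an insulin receptor substrate (-1.63, SE 0.30), and Sik1, a salt-inducible kinase (-1.55, SE 0.27). The ratios of Nr4a1 on arrays 1 to 4 were -1.77, -1.15, 0.52 and 2.22, and those of Cfd -1.05, 0.91, 0.95 and 3.76. When each pair was left out, the difference ran from -3.83 to -1.02 for Cfd and from -2.11 to -0.99 for Sik1. All 12 genes had an adjusted p under 0.01 in this fit.

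This comparison rested on 2 arrays per sex. It called 0 features with Agilent's processed signals, the series matrix values, median centring or no dye term, and without replicate 1, 2 or 3. The fits without a replicate had no dye term, and the one without replicate 4 called 1032.

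**Figure D4:**
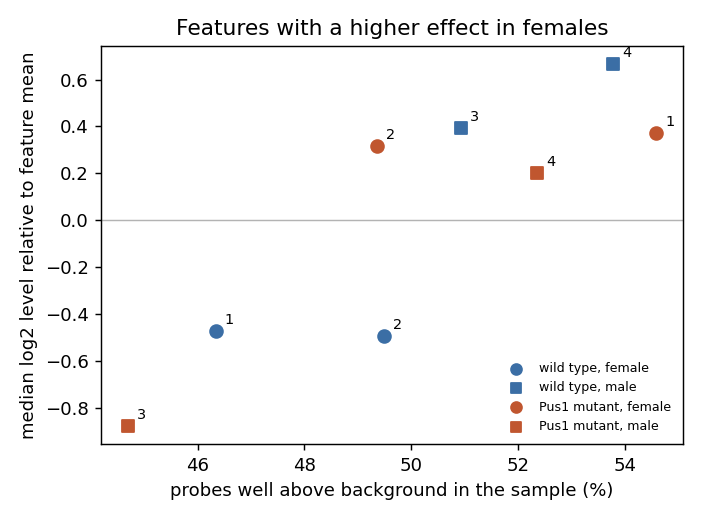
Median log2 level, relative to each feature's mean over the 8 samples, of the 2008 features with a higher mutant over wild-type ratio in females (y axis) against the percent of probes well above background in each sample (x axis). Numbers give the replicate, circles are females and squares males. The medians run from -0.88 in mutant replicate 3 to 0.67 in wild-type replicate 4. The median and the percent correlated at 0.86 over the 8 samples (Pearson, exact permutation p = 0.00642). The features were chosen for their pattern over these samples and count in the percent, so that this is no independent test of the relation.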

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

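The tests on the genes with the smallest p and on the features called between sexes were chosen only after the results were seen. The tests of called genes between genotypes were planned, with the 3 explanations named before the data were examined.

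The limma fit called a difference in the genotype effect between females and males for 2035 features. The count was 0 with processed signals, series matrix values, median centring and no dye term. The differences on the log2 scale, females minus males, were 5.17 for 4933438K21Rik, 4.70 for H2-Q4, 4.56 for Tssk5, 4.47 for Gm10375, 4.45 for BC061237 and 4.05 for Slfn9. They were -2.83 for Nr4a1, -2.42 for Cfd, -1.94 for Atf3, -1.78 for Pdk4, -1.63 for Irs2 and -1.55 for Sik1. Those of 4933438K21Rik and BC061237 are inexact, since each rests on a level not well above background. One sample stood far from the other 3 of its genotype in 14 of 102 groups tested. Chance flags about 1 in 20 of independent groups, and these were not independent, since several genes chosen for extreme ratios moved in parallel. Mutant replicate 3 was the low sample for 4933438K21Rik (normalized log2 level 6.60, not well above background), Tssk5 (7.91), Gm10375 (6.997), BC061237 (6.85, not well above background) and Slfn9 (9.97). It was also low for the median of the 2008 features (-0.88 relative to their means). Wild-type replicate 4 was low for Nr4a1 (11.18) and Sik1 (8.11). Wild-type replicate 2 was high for Psph (9.17) and for Upk3b (8.68), Scd1 (9.86) and Stard10 (9.62). Mutant replicate 1 was high for Timp1 (9.09), and wild-type replicate 1 for Pusl1 (8.83).

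The 2008 features with a higher effect in females were chosen for their pattern over the same samples, so that their levels do not test it. The medians in wild-type replicates 1 to 4 were -0.47, -0.49, 0.39 and 0.67, and in mutant replicates 1 to 4 they were 0.37, 0.32, -0.88 and 0.20. Of the 2008 features 66.5% had no RefSeq messenger RNA accession, against 35.7% of the others (one-sided Fisher exact p = 2.38e-156, with features not independent), so that uneven amounts of genomic DNA or unspliced RNA between samples may account for them. Their median log2 intensity was lower than that of the others by a difference of -0.46, which does not settle whether noise of dim probes contributes. Only 2 pairings of the 4 arrays could be fitted with the dye term, too few for a share under 0.05: the real one called 2035 and the other 0. The fit of the other pairing has the difference between sexes as its residual, so that its 0 is no separate evidence. A dependence of the genotype effect on sex remains open.

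Genes with the smallest p between genotypes lay near Pus1 more often than other genes. Of the 50 named genes with the smallest p, Pus1 left out, 13 lie within 20 Mb of it, against 2.15% of the other genes, and 9 lie 5 to 20 Mb away (one-sided Fisher exact p = 4.48e-08, with neighbouring genes not independent). No other stretch of the same length held as many (0% of 13118, the highest holding 4), which argues against a clustering that any stretch gives. These stretches were each centred on a gene and overlap widely, so that far fewer are separate. An effect of the altered allele on its closest neighbours alone is argued against by the 9 genes beyond 5 Mb. DNA of another strain that stayed linked to the mutant allele through the 5 backcross generations is a candidate explanation, and ratios of such genes, P2rx7 and its disagreeing probes included, may reflect strain differences in expression or under the probe. The count was 9 to 18 over the 19 alternatives.

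Between genotypes 0 features were called, with 223 at an unadjusted p under 0.05, fewer than a share of 0.05 of the features. With 0 named genes called, the planned test of their position near Pus1 could not be made. The 7 orientations of the arrays that could be fitted are too few for a share under 0.05. All 7 called at least the real 0, which any count would do, so that this tally decides nothing. The highest other orientation called 2194. That orientation turned both male arrays, which makes it the difference between females and males again, so that it is no separate evidence on chance or on the samples. A different share of atrium in the piece of heart taken was set up to explain called genes, of which there were 0, and its bounds left it undecided. Atrial markers had a median of 0.20, just past the bound of 0.2 set beforehand for that cause, while ventricular markers, at 0.02, had the same sign and lay within the bound of 0.1 set against it. The atrial medians on arrays 1 to 4 were -0.22, 0.39, -0.04 and 0.68. They were negative where the mutant was in Cy5 and positive where it was in Cy3. Their signs therefore follow the dye, and they neither show nor exclude a shift common to the mutants.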

How the results depend on the processing

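The restriction to RefSeq messenger RNA probes and the counts near Pus1 were chosen after seeing the data. Across 19 alternatives the Pus1 log2 ratio stayed negative, from -2.84 to -1.73, and from -1.97 to -1.73 when each pair was left out. It was past the threshold, as the 1 feature called, with median centring (-1.80), with a sex by genotype term (-1.85), with no replicate block (-1.85) and with the array as a random block (-1.85). The other 15 alternatives called 0 features between genotypes, the range without each pair being 0 to 0. The genotype by sex count of 2035 went to 0 with processed signals, series matrix values, median centring and no dye term, to 1244 with probes well above background in all 8 samples and to 712 with RefSeq messenger RNA probes, which tests fewer features. It was 0 to 1032 when each pair was left out, in the fit with no dye term and with the lone pair of a sex assumed to vary like the others. The count in females, 2 in the reported fit, was 0 with no background correction, processed signals, series matrix values, median centring, the mean over probes and no dye term, 894 with scale normalization, 419 with the strict filter, 1569 with a trend and robust prior, 331 with RefSeq messenger RNA probes, and 0 to 0 without each pair. The count in males, 737, was 0 with no background correction, processed signals, series matrix values, median centring and no dye term, 2 with the mean over probes, 1417 with scale normalization, 1829 with a trend and robust prior, 381 with RefSeq messenger RNA probes, and 0 to 299 without each pair. The 19 lists called by camera became 11 with no replicate block, 0 with an estimated correlation, 0 with fry, 7 to 19 without each pair, the 7 being without replicate 3, and at most 25, with median centring. Camera with the array as a random block was not run. The cause of these changes was not tested. Of 177 values of the 12 genes called between sexes 83 kept the call, 94 lost it and 0 turned. The 38 genes named between genotypes other than Pus1 had no call to lose, and all 720 of their values kept their direction. Between 44.7% and 54.6% of probes were well above background per sample, which limits what dim genes can show.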

Other observations

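The genes of this part were chosen after their values were seen. Atrial contractile genes varied widely between pairs. Myl7, the atrial myosin light chain gene, had mutant over wild-type log2 ratios of -1.49, 1.64, 0.20 and 4.28 on arrays 1 to 4, Myl4 of -1.57, 1.88, 0.38 and 5.77, and Sln, which encodes sarcolipin, of -1.57, 1.64, 0.58 and 5.10. The beta globin gene Hbb-b1 had ratios of 2.70, -3.50, -0.26 and -0.22, and Alas2, the erythroid enzyme of heme synthesis, of 1.92, -2.24, -1.15 and 0.38. None of these passed between genotypes in the limma fit. In the genotype by sex fit Myl7 (-2.17), Myl4 (-2.92) and Sln (-2.80, females minus males) passed (adjusted p = 0.00407 each), although the female ratios did not all lie below the male ones.

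Immediate early genes, a list set up like the glucocorticoid targets as a check of sample quality, had median ratios of -0.55, -0.21, 0.22 and 0.58 on arrays 1 to 4. Of the 44 lists 8 passed camera at a preset correlation for the difference between sexes, 7 of them lower in females and the interferon response higher, and 0 passed with an estimated correlation. Beside immediate early genes these were fetal and hypertrophic response genes (adjusted p = 0.00726), PPAR alpha and fasting targets (0.00850), atrial markers (0.0144), epicardium and mesothelium (0.0209), fatty acid oxidation (0.0314), other tRNA modification enzymes (0.0314) and the interferon response (0.0338). Camera compares a list with all other features, here with the 2008 higher in females among them, so that lower is relative to these. The other tRNA modification enzymes, for one, had 0 members called, with a median difference of -0.14 against -0.04 over all features. The difference of the immediate early genes, lower in females, passed camera at a preset correlation (adjusted p = 5.81e-08) but not with an estimated one (adjusted p = 0.762). Egr1 differed by -1.19 (SE 0.27, adjusted p = 0.0213 in limma) and Fos by -1.29 (adjusted p = 0.0227), females minus males.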
